A study of Mus musculus with 6 samples.

How the data were processed

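RNA from mouse colon in 6 libraries was compared, 3 labelled DMSO and 3 labelled lenvatinib. Total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V10 kit, per the labels' protocols. The deposited table holds FPKM values (fragments per kilobase of gene per 1000000 fragments) that the authors computed for 25339 genes, and all 6 of its columns were used. HTSeq, a read counter, and the mouse genome build GRCm39 are named per the submitters' processing notes. The HTSeq version, the aligner, the annotation, the strand setting and any filter are not given in the sources used here. The reference at hand was of another build, so no genome coordinates are printed, and genes are named by the symbols in the table.

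The labels call the libraries biological replicates and do not say which animal each came from. The p-values measure the spread between these libraries only, which for libraries 2 and 3 of each group may be technical.

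Depth was recovered from the values. In each gene the FPKM values were whole multiples of what 1 read is worth, within 0.01 reads, for 23942 of the 23951 genes above 0 (99.96%). The recovered totals were 37606962, 39231399 and 38571865 reads in genes for DMSO 1 to 3 and 37888623, 38668416 and 38351207 for lenvatinib 1 to 3. The product of total and step was constant across libraries within 0.0717%. Mitochondrial genes took 3.78 to 4.52% of these reads and the 10 most abundant genes 8.55 to 11.1%. At this depth counting error is small for abundant genes, but near 1 FPKM a short gene still rests on few reads.

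Libraries were compared in pairs by the recovered reads. For genes with at least 10 reads, the median squared deviation over that of counting noise was 2.61 between DMSO 2 and 3, 2.37 between lenvatinib 2 and 3, and 10.2 to 24.2 for the other pairs. Libraries 2 and 3 thus differed by more than counting noise, which does not show that they came from separate animals, since repeat libraries of the same RNA can exceed it too. The main test keeps the 3 libraries per group that the labels give. The pairs were averaged or blocked in alternatives chosen after seeing the data.

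Genes with a mean of at least 1 FPKM over the 6 libraries were tested (11774 genes) on log2(FPKM + 1), with a pseudocount of 1. The test was limma 3.58.1 in R 4.3.3, with a trended and robust variance prior, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. In advance, 41 gene lists were fixed for lenvatinib targets, cell types, pathways, RNA quality and tissues that a dissection could carry. Lists with at least 5 tested genes (38) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and compares with no other genes. With an estimated correlation, camera also uses the few residual degrees of freedom of the 6 libraries. At the preset correlation it uses those of the number of genes. List p-values were adjusted over the 38 lists. List members were also counted over all genes tested and adjusted over the list alone. Single values were compared by exact permutation over the 20 regroupings. The list of mitochondrial genes had no symbol in the table (0 of 13 matched), and those of skeletal muscle and exocrine pancreas had 3 and 2 tested genes, of which 0 passed, so they were not tested as lists.

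The main test, the gene lists, the other settings to be tried and the rule for named genes were set before the data were examined. The genes named are Madcam1 and the target kinases; the 12 largest increases and 12 largest decreases among genes that passed without overlap of the groups, leaving out unnamed gene models and antigen receptor segments; and up to 4 members of each list by unadjusted p. Ang4, Lcn2, Xist, Ddx3y and Nnt, and the genes of the follow-up lists on intestinal segments and follicles, were chosen after the main values were seen. Many genes that the rule selects are not printed, 1 of them for a reason outside the analysis.

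The test was tested on simulated data for 6 independent libraries, 3 against 3, with 11774 genes. Of 200 changed genes, 89% of the 100 changed by a factor of 2 and 94% of the 100 changed by a factor of 4 were recovered, with 6 false calls. In 20 simulations with no change, libraries 2 and 3 of each group came from the same animal. There the same test called 69.1 genes on average (130 at most) and 2.5 on average (13 at most) after averaging the pairs. All simulated genes were drawn independently of each other, while real genes can move together (estimated correlation 0.98 for the proliferation list). Counts from real data may vary more, so these are no bounds for them.

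Alternatives covered the pseudocount, the filter, 4 scalings, leaving out mitochondrial, haemoglobin and immunoglobulin genes, the variance prior, sample weights, the replicate number as a block, fold thresholds and each library left out. Added after seeing the data were the averaged and the randomly blocked pairs and limma voom on the recovered reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.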

Results

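Messenger RNA levels were measured by RNA sequencing in colon of mice that received either the solvent DMSO or lenvatinib, an oral inhibitor of receptor tyrosine kinases that include the VEGF, FGF and PDGF receptors, KIT and RET. Each of the 2 groups had 3 libraries, which the labels number as biological replicates. The recovered depth ranged from 37606962 to 39231399 reads in genes per library. The series title concerns colitis, the endothelial adhesion molecule MAdCAM-1 and B cell movement into the gut, so the comparison asks what the drug changed in the colon and whether these molecules and cells were among it. The labels do not say whether colitis was induced in these animals. Levels below are FPKM, given as mean ± SD over n = 3 libraries per group, and log2 fold changes are lenvatinib minus DMSO on the log2(FPKM + 1) scale, which understates the change of genes with low levels.

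The largest differences were a near loss of mucosal mast cell transcripts and a gain of transcripts typical of the small intestine in the lenvatinib libraries. As lists tested with a preset correlation, genes of macrophages and of fibroblasts and matrix were lower, and genes of fatty acid oxidation and the hypoxia response were higher. These calls were lost when the correlation was estimated, a version of camera with far fewer degrees of freedom (adjusted p = 0.344, 0.344, 0.115 and 0.344 with an estimated correlation). They passed with libraries 2 and 3 averaged at the preset correlation. There camera compares a list with the other genes, so averaging does not test it against the spread between libraries. Taking all 6 libraries as independent, fry called the first 3 lists (adjusted p = 0.00680, 0.00391 and 0.00250). It did not call hypoxia (0.0734), of which 3 of 24 genes passed. B cell genes were lower as a list with the preset correlation (adjusted p = 0.599 with an estimated correlation; fry 0.108), without any single gene passing the test. Madcam1 did not pass. In the limma test with Benjamini-Hochberg adjustment, 239 of 11774 genes changed, 129 higher and 110 lower, and all 239 had groups that did not overlap. An unadjusted p below 0.05 was found for 2586 genes (22%). Libraries 2 and 3 of each group were nearly identical. In simulated data with no change and such pairs drawn from the same animal, 17.2% of genes had an unadjusted p below 0.05 in this test. The simulated genes were independent of each other, unlike real genes, so this share is no bound for real data. Over all genes tested, 27.5% had groups that did not overlap, where chance gives 10% for 6 independent libraries. With each pair averaged, 34.9% did not overlap, where chance gives 33.3%. With the pairs averaged and each counted as 1 sample (2 against 2), 3 genes passed: Mcpt1 and Mcpt2, both lower, and Fabp6, higher. With the pairs kept as a random block, 46 genes passed, and all 46 were among the 239.

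The near identity was measured as the coefficient of variation between libraries beyond counting noise. It was 2.81% between DMSO 2 and 3 and 2.36% between lenvatinib 2 and 3, against 9.25 to 14.4% for every other pair. Lenvatinib 1 differed from the DMSO libraries by 9.30 to 9.62%, and from lenvatinib 2 and 3 by 13.5 and 13.7%. DMSO 1 also stood apart as the only library with more than a trace of Y-linked transcripts (Ddx3y 6.54 FPKM, and listed at 0 in the other 5) and almost no Xist (0.00147 against 15.9 to 19.8 FPKM). The DMSO means and SDs, and the DMSO side of the 2 against 2 test, therefore include a library that differs from all others in sex-linked transcripts. Without DMSO 1, 270 genes passed, 153 of them among the 239.

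**Figure D1:**
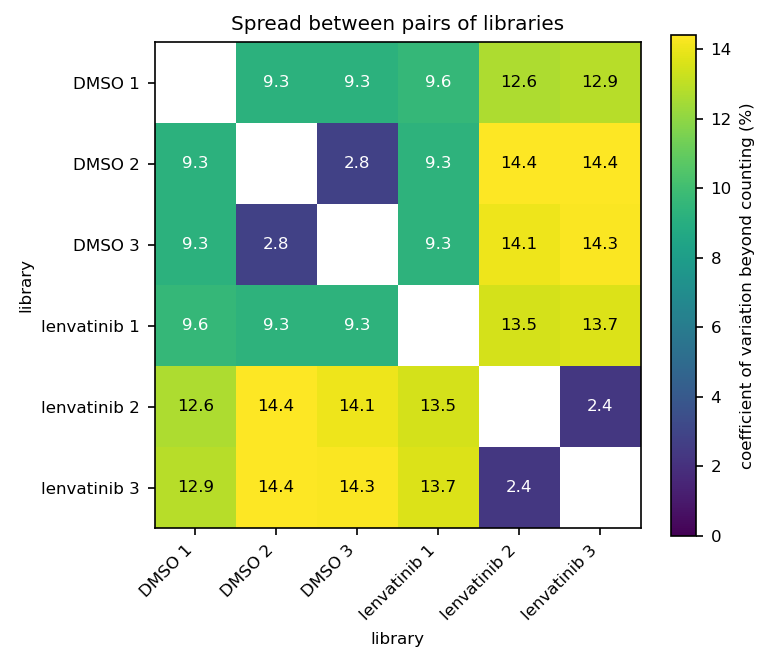
Coefficient of variation beyond counting noise, in percent, for each pair of the 6 libraries over genes with a mean of at least 500 reads in the pair, with libraries on both axes. The pairs DMSO 2 and 3 (2.81%) and lenvatinib 2 and 3 (2.36%) lie far below all others (9.25 to 14.4%).

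Madcam1 encodes the adhesion molecule that lets lymphocytes expressing the integrin α4β7 leave gut venules. It measured 2.70, 4.52 and 3.97 FPKM in DMSO 1 to 3 and 3.70, 2.11 and 2.65 FPKM in lenvatinib 1 to 3. The difference of −0.31 on the log2 scale was not larger than the spread between libraries by test (exact permutation test, two-sided p = 0.2, where 0.1 is the smallest p that 3 against 3 allows; 0.667 with the pairs averaged; limma adjusted p = 0.380). Among 16 tested vascular adhesion molecules 1 fell (2 lower when adjusted over the list alone) and 15 did not pass. The gene that fell was Fut4, a fucosyltransferase of selectin ligands, from 7.65 ± 0.539 to 4.67 ± 0.326 (log2 fold change −0.61). Chst2, Chst4 and Ackr1 did not pass, and the list as a whole did not either (camera adjusted p = 0.194). Of 15 tested gut homing receptors and chemokines, 2 rose (2 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.792). They were the epithelial chemokines Ccl25, from 1.07 ± 0.400 to 3.17 ± 0.0821, and Ccl28, from 22.3 ± 0.750 to 30.6 ± 1.71, which attract gut-homing lymphocytes. Ccl25 is also a gene of small intestinal enterocytes, and it rose together with the small intestinal transcripts described below. The homing receptor Cxcr4 and the chemokine Cxcl16 did not pass.

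B cell transcripts were lower in the lenvatinib libraries: all 16 tested genes of the list had negative fold changes, with a mean of −1.28. None of the 16 passed in limma over all genes tested, and 14 were lower when adjusted over the list alone. Of the 4 that the naming rule selects, Ms4a1, Blk, Bank1 and Spib, all 4 passed without lenvatinib 1 (adjusted p = 2.18e-04 to 0.00215) and with sample weights, and Blk and Spib with quantile normalization (0.0493 and 0.0466). Over all 11774 genes tested, 4479 passed without lenvatinib 1 and 7582 with sample weights, so those passes are not particular to B cell genes. Ms4a1, which encodes CD20, measured 8.05 ± 0.866 and 1.72 ± 1.85 (adjusted p = 0.0896), and Blk, a B cell kinase, 1.98 ± 0.168 and 0.459 ± 0.455. The list passed with the preset correlation (camera adjusted p = 1.48e-06), also with the pairs averaged, and was lost when it was estimated (adjusted p = 0.599 with an estimated correlation) and with fry (0.108). The mean level of the list was 2.61, 2.75 and 2.82 in DMSO 1 to 3 and 2.29, 0.97 and 1.06 in lenvatinib 1 to 3 on the log2 scale (exact permutation test, two-sided p = 0.1, the smallest possible, and 0.333 with the pairs averaged, the smallest that 2 against 2 allows). If the study picked B cells or vascular adhesion from these same samples, neither list is independent evidence of its direction. Vpreb3, a chaperone of the B cell receptor complex outside the list, measured 3.54 ± 0.745 and 0.631 ± 0.529 (log2 fold change −1.52). It passed narrowly (limma adjusted p = 0.0480), and the call was lost in 15 of 21 alternatives, among them 5 of the 6 that leave out a library, all but the one without lenvatinib 1 (1.94e-04 to 0.641 over the alternatives).

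Plasma cell and antigen presentation genes had the same direction. None of 13 plasma cell genes and none of 12 MHC class II genes passed in limma, and 0 and 3 were lower when adjusted over the list alone (5 and 3 at an unadjusted p below 0.05). Tnfrsf13b, a receptor for B cell survival factors, measured 5.77 ± 1.69 and 2.08 ± 1.58, and H2-DMb2, which helps load peptides, 11.6 ± 1.62 and 4.25 ± 2.02. As lists both were lower (camera adjusted p = 0.00445 and 0.00366; adjusted p = 0.621 for each with an estimated correlation). Library lenvatinib 1 lay within the DMSO range for both lists, at 3.98 against 3.95 to 4.56 and at 5.58 against 5.30 to 5.68 on the log2 scale. The mean change of the MHC class II list was −1.02, or −1.55 without lenvatinib 1. The plasma cell call was lost without DMSO 1 (adjusted p = 0.0845; 5.61e-06 to 0.0845 over the 22 alternatives). T and NK cell genes did not pass as genes (0 of 17, also 0 when adjusted over the list alone or at an unadjusted p below 0.05) or as a list (camera adjusted p = 0.0886). Their mean was highest in lenvatinib 1, at 3.21, and lowest in lenvatinib 2 and 3, at 1.26 and 1.33, with DMSO at 2.38 to 2.87. Genes of lymphoid follicle organisation, such as Ltb and Ccl19, did not pass either (0 of 14, also 0 when adjusted over the list alone and 1 at an unadjusted p below 0.05; camera adjusted p = 0.986).

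Mast cell transcripts nearly disappeared: all 5 tested genes of the mast cell and eosinophil list fell (5 lower when adjusted over the list alone), by a mean of −3.75. Mcpt1, the chymase of mucosal mast cells, fell from 148 ± 12.9 to 0.241 ± 0.273 (log2 fold change −6.92, SE 0.160), and Mcpt2 from 55.1 ± 1.43 to 0.113 ± 0.0645 (−5.66, SE 0.0697; adjusted p = 1.13e-06). The carboxypeptidase Cpa3 fell from 4.11 ± 0.560 to 0.0522 ± 0.0297. Fcer1a, the α chain of the IgE receptor, fell from 2.45 ± 0.559 to a level listed at 0 in all 3 lenvatinib libraries. Cma2, Mcpt4 and Mcpt9 were also among the 12 largest decreases. Reads of these similar proteases could be split between family members, so single members are uncertain. The list passed (camera adjusted p = 1.02e-10; adjusted p = 0.0842 with an estimated correlation; fry 4.39e-06). Kit, for the growth factor receptor of mast cells, measured 7.96 ± 0.231 and 6.28 ± 0.317 and did not pass (adjusted p = 0.0830).

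Macrophage transcripts were lower: 10 of 17 tested macrophage and monocyte genes fell and none rose (13 lower and 1 higher when adjusted over the list alone). C1qc and C1qa, which encode chains of complement C1q, fell from 80.7 ± 5.91 to 33.9 ± 4.63 and from 109 ± 10.3 to 47.4 ± 7.93. Cx3cr1, the fractalkine receptor, fell from 8.04 ± 0.535 to 2.11 ± 0.348, and the mannose receptor Mrc1 from 9.17 ± 0.335 to 3.47 ± 0.387. The list passed (camera adjusted p = 5.05e-09; adjusted p = 0.344 with an estimated correlation; fry 0.00680). Outside the list, the monocyte-attracting chemokine Ccl8 fell from 124 ± 12.7 to 26.4 ± 14.1, and the chemokine Pf4 from 17.7 ± 2.81 to 5.27 ± 0.793. Of 12 inflammatory mediators, only the collagenase Mmp13 fell, from 3.85 ± 0.605 to 1.43 ± 0.343 (1 lower when adjusted over the list alone; camera adjusted p = 0.792). Of 6 neutrophil genes, only Mmp9 fell (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.227), and the median and mean of that list were above 0 while fry pointed lower. Among 26 interferon response genes none passed, also when adjusted over the list alone (1 at an unadjusted p below 0.05; camera adjusted p = 0.229, direction higher, median 0.05, mean −0.03).

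In limma none of the genes for 10 kinases that lenvatinib inhibits passed, and 3 were lower when adjusted over the list alone (camera adjusted p = 0.180). Among the alternatives, Kdr passed with quantile normalization (0.0390), with voom (0.0492), with sample weights and without lenvatinib 1 (0.00211). Flt1, Kit and Fgfr4, lower, and Fgfr2, higher, passed with sample weights and without lenvatinib 1, and Pdgfra, lower, with sample weights only. With sample weights 7582 of all 11774 genes tested passed, and 4479 without lenvatinib 1, so passing there is not particular to the kinases. Kdr, which encodes VEGF receptor 2, measured 3.94 ± 0.571 in DMSO and 1.71 ± 0.559 in lenvatinib (log2 fold change −0.88, adjusted p = 0.0609). Flt1, for VEGF receptor 1, measured 1.77 ± 0.0552 and 1.03 ± 0.237 (adjusted p = 0.0922). Kdr and Flt1 were lower in each lenvatinib library than in any DMSO library. Flt4 measured 2.15 ± 0.0288 and 2.52 ± 0.981, Fgfr1 3.99 ± 0.488 and 4.05 ± 0.799, Fgfr2 50.7 ± 1.86 and 59.8 ± 7.22, and Fgfr3 3.80 ± 0.503 and 3.50 ± 0.575. Fgfr4 measured 2.63 ± 0.0986 and 2.11 ± 0.207, Pdgfra 12.9 ± 2.504 and 9.97 ± 1.69, and Ret 1.65 ± 0.0906 and 1.48 ± 0.226.

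Among 22 tested genes of vascular endothelium only Cd93, a surface lectin, fell, from 5.90 ± 0.142 to 2.87 ± 0.636 (5 lower when adjusted over the list alone; camera adjusted p = 0.111). Of 15 VEGF-responsive genes 1 fell, the potassium channel subunit Kcne3, from 31.3 ± 0.777 to 14.6 ± 1.51 (1 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.0808). Kcne3 is also expressed by colonic epithelium. Of 8 lymphatic genes only the scavenger receptor Stab1, which macrophages also express, fell, from 8.33 ± 0.329 to 2.80 ± 0.296 (1 lower when adjusted over the list alone; camera adjusted p = 0.986). The median of that list was 0.01 and its mean −0.16, and camera pointed higher and fry lower. Vegfa rose from 8.14 ± 0.355 to 12.7 ± 1.03 (log2 fold change 0.58), the only 1 of 11 ligand genes that passed (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.305, direction higher, median −0.10, mean 0.01). Hypoxia response genes were higher: 3 of 24 rose and none fell (10 higher and 1 lower when adjusted over the list alone). Besides Vegfa these were the hexokinase gene Hk2, from 48.7 ± 2.46 to 70.3 ± 2.13, and Ankrd37, from 4.14 ± 0.770 to 15.5 ± 6.50. The list passed with camera (adjusted p = 1.73e-08; adjusted p = 0.344 with an estimated correlation) and not with fry (0.0734).

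**Figure D2:**
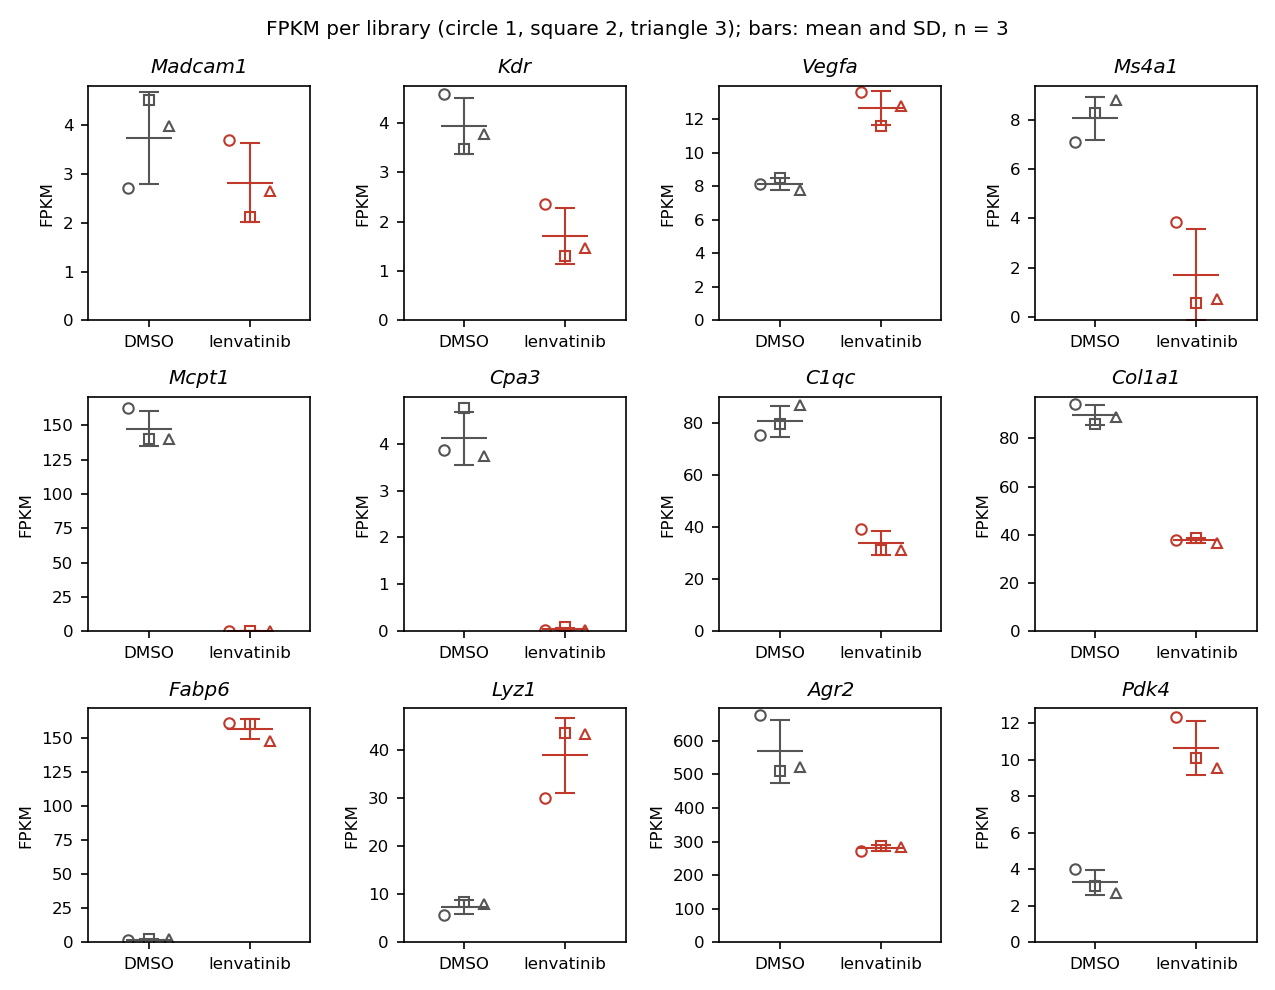
FPKM (vertical axes, linear from about 0) of 12 genes in each of the 6 libraries, by treatment; symbols are libraries 1 to 3 and bars the mean and SD of n = 3. Mcpt1 and Cpa3 are near 0 and Fabp6 near 156 FPKM in the lenvatinib libraries, while the Madcam1 values of both groups overlap.

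Transcripts of the small intestine rose: 6 of 10 tested genes of the list passed (9 higher when adjusted over the list alone), with a mean change of 2.58. Fabp6, the ileal bile acid binding protein, rose from 2.00 ± 0.477 to 156 ± 7.48 (log2 fold change 5.73, SE 0.126; adjusted p = 2.01e-05). The defensin gene Defa24 measured 1.13, 0 and 0 FPKM in DMSO 1 to 3 and 94.8, 139 and 124 FPKM in lenvatinib 1 to 3, and lysozyme Lyz1 rose from 7.34 ± 1.48 to 39.0 ± 7.77. In total 9 α-defensin genes rose, and Defa39 was listed at 0 in every DMSO library. These genes are near-identical copies whose reads could be split, so single members are uncertain. Apoa1, an apolipoprotein of enterocytes, rose from 0.315 ± 0.166 to 28.8 ± 19.6 (adjusted p = 0.0441), and the peptidase Naaladl1 from 0.890 ± 0.563 to 17.1 ± 7.03. Mptx2 and the defensin-processing protease Mmp7 rose as well. The list passed (camera adjusted p = 1.07e-14; adjusted p = 0.187 with an estimated correlation; fry 0.00187).

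Among 22 genes of absorptive colonocytes 2 rose (6 higher and 1 lower when adjusted over the list alone): Guca2b, for uroguanylin, from 20.4 ± 1.16 to 37.0 ± 2.66, and the bile acid exporter subunit Slc51a from 40.5 ± 2.97 to 83.6 ± 13.0. Both rose together with the small intestinal transcripts above, and whether they share that source was not tested. Goblet cell genes were lower, with 2 of 20 falling and none rising (1 higher and 6 lower when adjusted over the list alone). The mucin-folding enzyme Agr2 fell from 569 ± 93.6 to 281 ± 8.32 and the secretory regulator Creb3l1 from 36.7 ± 1.02 to 22.7 ± 1.502. Clca1 measured 1973, 329 and 334 FPKM in DMSO 1 to 3 and 52.4 to 62.4 FPKM with lenvatinib, and did not pass (adjusted p = 0.0791). The colonocyte list was higher (camera adjusted p = 4.20e-05; adjusted p = 0.344 with an estimated correlation) and the goblet list lower (camera adjusted p = 0.00366; adjusted p = 0.621 with an estimated correlation). Lenvatinib 1 lay within the DMSO range of the colonocyte list, at 7.25 against 7.17 to 7.26 on the log2 scale. The goblet list stood highest in DMSO 1, at 7.36 against 6.42 and 6.46 in DMSO 2 and 3 and 5.78 to 6.10 with lenvatinib, and its mean change was −0.75, or −0.45 without DMSO 1. The goblet call was lost without lenvatinib 1 (adjusted p = 0.366; 7.59e-10 to 0.535 over the 22 alternatives).

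All 23 proliferation genes had negative fold changes, and none passed over all genes or when adjusted over the list alone (5 at an unadjusted p below 0.05). Mki67 measured 21.1 ± 1.72 and 11.01 ± 8.66. The list was lower (camera adjusted p = 4.08e-04; adjusted p = 0.621 with an estimated correlation), but lenvatinib 1, at 4.18, lay within the DMSO range of 3.87 to 4.23. The mean change of the list was −0.83, or −1.29 without lenvatinib 1. None of 14 stem cell and Wnt target genes passed (0 when adjusted over the list alone, 4 at an unadjusted p below 0.05; camera adjusted p = 0.226). Among 18 tight junction genes none passed (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.226, direction higher, median 0.04, mean −0.01). None of 18 antimicrobial genes passed (3 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.180). Reg3b, a secreted lectin, measured 1068, 174 and 172 FPKM in DMSO and 1819 to 2047 FPKM in lenvatinib. The list of 11 enteroendocrine and tuft cell genes did not pass with camera (adjusted p = 0.0886) and passed with fry (0.00680, direction lower).

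In the stroma, 9 of 21 fibroblast and matrix genes fell and none rose (15 lower when adjusted over the list alone). Col1a1 fell from 89.6 ± 4.16 to 37.7 ± 1.15 (log2 fold change −1.23, SE 0.0606), Col3a1 from 167 ± 4.002 to 85.9 ± 1.52, and the proteoglycan gene Lum from 22.9 ± 1.43 to 11.5 ± 0.411. The list passed (camera adjusted p = 5.05e-09; adjusted p = 0.344 with an estimated correlation; fry 0.00391). Smooth muscle genes were slightly higher as a list, with a mean of 0.12 and 0 of 15 passing (0 when adjusted over the list alone, 3 at an unadjusted p below 0.05; camera adjusted p = 0.00216; adjusted p = 0.599 with an estimated correlation). Lenvatinib 1, at 6.39, lay within the DMSO range of 6.32 to 6.46. The smooth muscle call was lost with quantile normalization (adjusted p = 0.0527; 2.16e-05 to 0.0527 over the 22 alternatives). None of 10 pericyte genes, 6 genes of the interstitial cells of Cajal or 8 genes of enteric neurons and glia passed (0, 1 and 0 when adjusted over the list alone, 2, 2 and 1 at an unadjusted p below 0.05; camera adjusted p = 0.0886, 0.231 and 0.194).

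**Figure D3:**
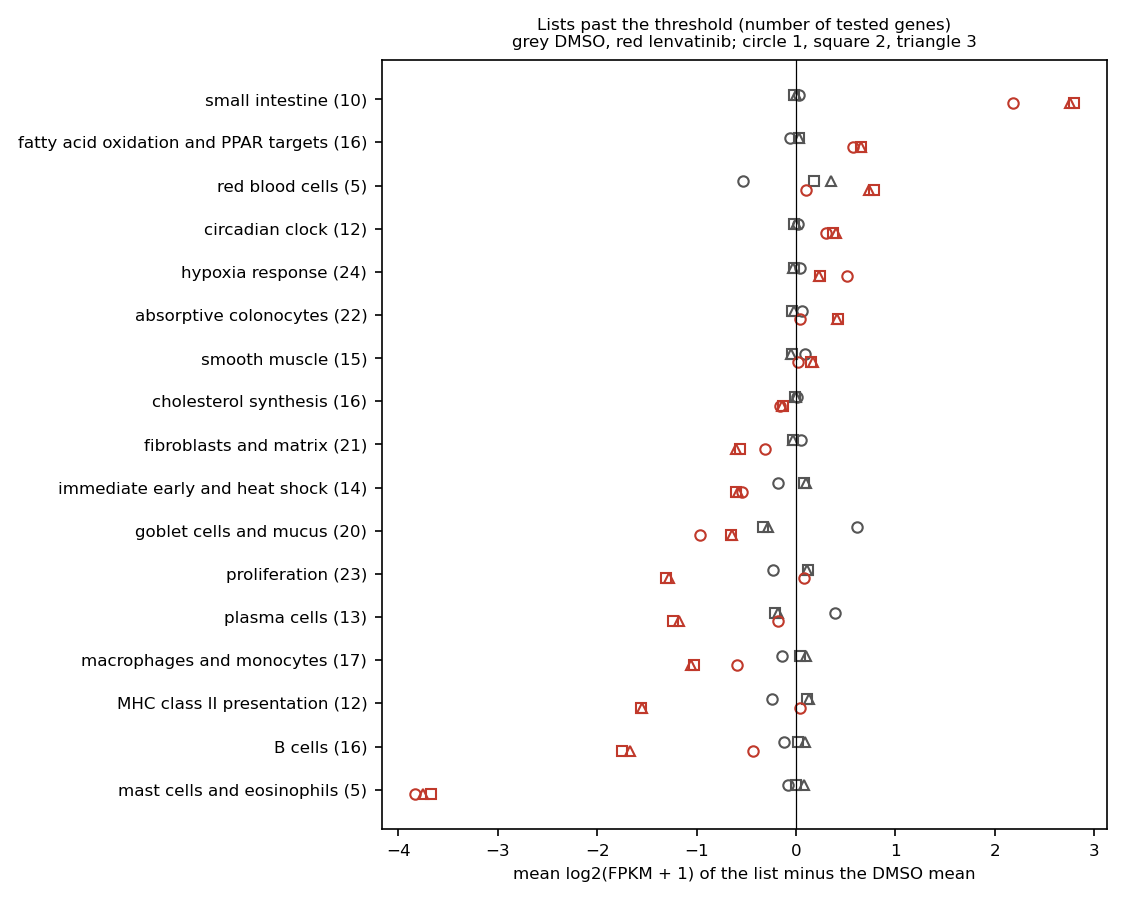
Mean log2(FPKM + 1) of each of the 17 lists past the camera threshold, per library, minus the mean of the DMSO libraries (horizontal axis); symbols are libraries 1 to 3. Lenvatinib 1 sits with the DMSO libraries for proliferation and MHC class II, and with lenvatinib 2 and 3 for mast cells and fatty acid oxidation.

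In all, 17 of 38 tested lists passed with the preset correlation, 7 higher and 10 lower. With an estimated correlation none of them held (0 lists, smallest adjusted p = 0.0842; 6 at an unadjusted p below 0.05), while fry called 9 lists, 8 of them among the 17. The 9 of the 17 that fry did not call were B cells, plasma cells, MHC class II, hypoxia, colonocytes, goblet cells, proliferation, smooth muscle and red blood cells (fry adjusted p = 0.0734 to 0.257). With libraries 2 and 3 averaged 20 lists passed at the preset correlation, the 17 among them, which does not test them against the spread between libraries.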

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

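The averaged pairs, the random block and voom were chosen after the data were seen; the other settings here were planned. The count of 239 changed genes lay between 164 and 303 with other pseudocounts, scalings, mean filters of at least 0.1 or 5, priors and voom (236 genes, 213 of them among the 239). It fell to 140 genes with no filter, where 23951 genes are tested, to 77 with a log2 fold change of at least 1, to 46 with libraries 2 and 3 as a random block and to 3 with them averaged. It was 7582 with sample weights, a setting that takes the near-identical libraries 2 and 3 as independent. The cause was not tested. Leaving out 1 library gave 45 genes (without DMSO 3) to 4479 (without lenvatinib 1), and 50, 58, 57 and 270 without DMSO 2, lenvatinib 2, lenvatinib 3 and DMSO 1. The 45, 50, 57 and 58 genes come from settings that lack 1 of a near-identical pair. Without lenvatinib 1 the lenvatinib group consists of that near-identical pair, so its spread is small. All 239 genes had an unadjusted limma p below 0.05 in the averaged setting, in which 647 genes (5.5%) did, but the same libraries had selected them. Their direction could not change with averaging, since the groups of all 239 did not overlap. Of the 57 genes that passed and that the naming rule selects, 31 lost the call in at least 1 setting that leaves out a library, and 3 (Mcpt1, Mcpt2 and Fabp6) kept it in all settings. Of the 118 it selects that were tested and did not pass, 104 passed with sample weights, 80 without lenvatinib 1 and 23 in another setting, among them Clca1 (0.00202) and Reg3b (4.57e-04) without DMSO 1.

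Lists past the threshold numbered 15 to 23 in the settings that keep camera's preset correlation, 0 with an estimated correlation and 9 with fry. The estimate lay below the preset 0.01 for mast cells (−0.0359), cholesterol synthesis (−0.0373), circadian clock (−0.0118) and immediate early genes (−0.0739). A higher correlation therefore cannot account for the loss of these calls. For the others of the 17 lists the estimate was 0.114 to 0.98. The versions of camera also differ in degrees of freedom, which are far fewer with an estimated correlation. For the lists with an estimate below the preset value, the fewer degrees of freedom remain as a source of the loss. The share of each part in the other lists, and the cause of the fry count, were not tested. Single lists were lost without 1 library: red blood cells without DMSO 1 (adjusted p = 0.0698, mean change 0.27 against 0.54), and cholesterol synthesis (0.283) and immediate early genes (0.208) without lenvatinib 1. The Madcam1 difference stayed negative in all 21 alternatives, from −0.61 to −0.15. It passed with sample weights only, at −0.61 (limma adjusted p = 0.00118; 0.00118 to 0.968 over the alternatives), and the cause was not tested. That setting takes the near-identical libraries 2 and 3 as independent. With them averaged the difference was −0.15 (limma adjusted p = 0.938), so the pass is no firm evidence of a fall. The B cell list mean stayed between −1.94 and −1.04 in its 17 alternatives. Cela1, a pancreatic elastase gene at −0.02, turned to 0.18 with sample weights and ranged from −0.13 to 0.17 with 1 library left out, 0.17 without lenvatinib 1; the cause was not tested.

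Deviations from the group means correlated at −0.20, −0.16 and −0.15 for equal replicate numbers, and no library correlated best with its own number. These correlations cannot decide whether replicate numbers pair the libraries. Deviations cancel within a group and each group holds a near-identical pair, so the correlations are not separate observations. With the replicate block, 29 genes passed, 27 of them among the 239. Depth was alike in all libraries, so it limits mainly genes near or under 1 FPKM, where few reads can decide a value.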

Other observations

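Tests chosen only after the result was seen were those of immune cells of every kind, of a shared animal or pool and of the sample splits, and every value with libraries 2 and 3 averaged or without genes of other lists; the segment and follicle tests were set after the main values were seen and before those of their own genes were looked at.

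Genes of fatty acid oxidation rose in the lenvatinib libraries: 8 of 16 tested genes passed, none fell (12 higher when adjusted over the list alone), and all 16 had positive fold changes. Pdk4, the kinase that restrains glucose oxidation, rose from 3.28 ± 0.676 to 10.7 ± 1.49 FPKM (mean ± SD, n = 3), Acot1 from 5.72 ± 0.979 to 14.0 ± 2.23 and Acaa2 from 104 ± 4.43 to 165 ± 17.4. The list passed (limma camera, Benjamini-Hochberg adjusted p = 1.07e-14; adjusted p = 0.115 with an estimated correlation; fry 0.00250). Of 12 circadian clock genes 4 rose and none fell (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 2.13e-04; adjusted p = 0.164 with an estimated correlation). These were Dbp, from 1.33 ± 0.152 to 3.70 ± 0.422, Tef, Nr1d1, from 6.63 ± 0.582 to 16.0 ± 2.76, and Nr1d2. The labels give no time of day for tissue collection.

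Of 16 cholesterol synthesis genes Hmgcs1 fell, from 84.0 ± 1.51 to 63.8 ± 3.25 FPKM (4 lower when adjusted over the list alone; camera adjusted p = 0.0126; adjusted p = 0.261 with an estimated correlation). Of 14 immediate early and heat shock genes Fos fell, from 68.3 ± 3.46 to 39.6 ± 2.20 (5 lower when adjusted over the list alone; camera adjusted p = 0.00366; adjusted p = 0.204 with an estimated correlation). None of 15 unfolded protein response genes passed (4 lower when adjusted over the list alone; camera adjusted p = 0.0886), nor did any of 9 adipose genes (2 higher when adjusted over the list alone; camera adjusted p = 0.0587). None of 5 red blood cell genes passed (0 when adjusted over the list alone, 1 at an unadjusted p below 0.05), while their list was higher (camera adjusted p = 0.00648; adjusted p = 0.599 with an estimated correlation). Its mean in lenvatinib 1, at 3.58, lay within the DMSO range of 2.94 to 3.82, and the lowest was DMSO 1. The antimicrobial ribonuclease gene Ang4 measured 1672 FPKM in DMSO 1 against 51.2 and 55.3 in DMSO 2 and 3 and 6.69 to 14.3 with lenvatinib. Nnt, a mitochondrial transhydrogenase, measured 5.24 FPKM in DMSO 1 and 17.8 to 18.8 in the other libraries, so the DMSO group is mixed in this gene as in its sex-linked transcripts. Lcn2, an inflammation marker, measured 44.4 FPKM in lenvatinib 1 and 1.92 to 5.34 in the other libraries.

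The small intestinal transcripts may come from ileal tissue in the lenvatinib pieces. All 13 tested of 20 further ileal enterocyte genes were higher, with a median log2 fold change of 0.71 at percentile 100 of 10000 random lists matched on level, and at percentile 100 with libraries 2 and 3 averaged, and so were the 12 in no other list; 11 of the 13 had at least 1 FPKM in DMSO colon too. For a more proximal piece of colon, posterior HOX genes had a median log2 ratio of −0.109 (SE 0.150, over genes and not libraries). By the rule set beforehand this counts against such a piece, as it lies above −0.5 by more than the SE. The direction of single genes was not part of that rule. Of 8 genes, 5 were lower and 3 higher, with Hoxa10 at 17.8 FPKM in DMSO and 10.9 in lenvatinib. A median near 0 of such mixed genes does not decide, so this explanation stays open. An effect of lenvatinib on the epithelium, with small intestinal genes arising in the colon, was not tested and stays open.

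B cell transcripts could be lower because the lenvatinib pieces held fewer lymphoid follicles. The 11 tested follicle genes, 6 of which are in other lists, had a median log2 fold change of −0.27, at percentile 0.57 of random lists, but at percentile 35.4 with libraries 2 and 3 averaged; the 5 in no other list lay at 4.11 and 42.5. In lenvatinib 1 their median lay 0.08 above the DMSO mean, and in lenvatinib 2 and 3 it was −0.64, so the test rests on that pair. A loss of immune cells of every kind was not excluded: the B cell and macrophage lists did not differ beyond error (difference −0.264, SE 0.412, pairs averaged). That difference was 0.148 in lenvatinib 1 and −0.676 in lenvatinib 2 and 3, each against the DMSO mean. The comparison covers these lists only and cannot speak for other immune cells. The T and NK cell list, which did not pass, stood at 3.21 in lenvatinib 1, above DMSO (2.38 to 2.87). In lenvatinib 2 and 3 it stood below DMSO, at 1.26 and 1.33, so lenvatinib 1 showed no loss of these genes. Mast cell genes were lower in all lenvatinib libraries. The neutrophil list, which did not pass, was higher by 0.53, or by 0.30 without lenvatinib 1, with lenvatinib 2 and 3 (2.11 and 2.21) below DMSO 1 (2.32). A lower entry of B cells under lenvatinib was not tested apart from these and stays open.

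Libraries 2 and 3 of each group may have been made from the RNA of 1 animal or 1 pool. The larger of their 2 coefficients of variation beyond counting was 0.0281, but littermates kept alike cannot be told apart from this by the values alone, as no known technical repeat is at hand for comparison. Of the 10 splits of the 6 libraries into 3 and 3, the real 1 gave 239 genes and the highest of the others 46 (DMSO 1 with lenvatinib 2 and 3 against the rest), and 10 splits are too few for a share under 0.05. Only these 2 splits keep both near-identical pairs whole. Every other split parts the libraries of a pair and gave 0 genes, so those counts are no fair comparison for the real split. If the pairs are repeats, the design holds 2 animals or pools per group, and the counts that do not take them as independent are 3 genes with the pairs averaged and 46 with the random block.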
